A study of Homo sapiens with 39 samples.

How the data were processed

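Total RNA of 2 human B-lineage cell lines was measured on Illumina BeadChip arrays, 39 in all, 19 from IM-9 and 20 from U266. Per the labels, IM-9 was sensitive and U266 tolerant to ch128.1Av, an antibody fusion protein directed at transferrin receptor 1. Cells were taken untreated at 0 h and again at 1, 3, 9 and 24 h of exposure to buffer or to ch128.1Av at 10 nM, which gave 18 groups. Groups held 2 arrays each, except 3 arrays for ch128.1Av at 3 h in IM-9 and at 1 and 9 h in U266. No pairing of treated with control arrays by replicate number was assumed.

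The deposited scanner table held the mean intensity of each of 20589 probes per array, on a linear scale, neither background-subtracted nor normalized between arrays, per the file headers and as checked on the values. BeadStudio is named in the labels, with no version. The same deposited table held a detection score per probe and array, a fraction between 0 and 1 near 1 for most bright probes. The detection p was taken as 1 minus this score. Some bright probes failed it: 197 probes had a detection p of 0.01 or more on an array where they were among the 5000 brightest. A second deposited table held log2 values that the authors had quantile-normalized between arrays, as found from the values, since no label states this step. Within each array its rank order matched that of the scanner table with a correlation of 1, and it served as an alternative source. A further 78 columns of per-sample values were not used.

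Gene symbols came from a reference table that pairs the array's probes with symbols. Of the probes, 18332 carried 1 symbol and 2257 none, for 16591 distinct symbols. Intensities were background-corrected with the detection p, given an offset of 16, quantile-normalized and set on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.01 on at least 2 arrays were kept, which kept 12080 and removed 8509. For 520 genes with more than 1 kept probe, the probe with the highest mean was used. This left 11538 probes for testing, 10399 with a gene name and 1139 without. Some genes were not analysed here. No genome positions are given, since the deposited tables hold none that were used.

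One linear model with a mean for each of the 18 groups was fitted with lmFit and eBayes of limma, with 21 residual degrees of freedom, so that the spread was pooled over all groups. The moderated test of limma was two-sided, p values were adjusted by Benjamini-Hochberg over all genes tested within each of 15 contrasts, and genes with an adjusted p under 0.05 were called. The contrasts were ch128.1Av against buffer at each of 4 hours in each line, the difference between the lines in that effect at each hour (IM-9 minus U266), the lines against each other at 0 h, and the buffer controls at 24 h against 0 h in each line. These p values measure the spread between samples of a group, which may be technical, since the labels do not say whether replicates were separate cultures. For arrays, their number limits the precision.

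Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, two-sided, adjusted over the 20 lists within a contrast, and again with an estimated correlation. The lists were iron uptake, storage and iron regulatory protein; hypoxia and HIF-1 targets; p53 targets; G1/S and DNA replication; G2/M and mitosis; ATF4 and integrated stress response; endoplasmic reticulum unfolded protein response; BCL2 family and caspases; NF-kB targets; immediate early genes; cholesterol biosynthesis and SREBP-2 targets; respiratory chain subunits; iron-sulfur cluster and heme synthesis; heat shock response; NRF2 and metallothionein oxidative stress response; MYC and ribosome biogenesis; interferon-stimulated genes; B cell identity; plasma cell identity; and T, NK, myeloid, erythroid, epithelial and stromal markers. List members were counted as risen or fallen at an adjusted p under 0.05 over all genes and again adjusted over the list alone.

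Genes were named by a rule. TFRC, FTL, BNIP3, NDRG1, CDKN1A, DDIT3, BBC3, MKI67 and MYC were always followed. For each treatment contrast, up to 8 risen and 8 fallen genes with the largest called change and no overlap between treated and control arrays were eligible. For each list, the 4 members with the smallest p at the hour with most calls in each line were eligible. For each difference between lines, 5 positive and 5 negative genes were eligible, for the lines at 0 h the 10 highest in each, and for the controls 5 risen and 5 fallen. The contrasts, thresholds, lists and rule were chosen before the data were examined, and the few genes named outside the rule are marked as chosen after their values were seen. A fold against a line in which a gene passed detection on neither array was computed against the lowest level that passed detection on those arrays, where that was the higher, and is written as "at least".

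On simulated data for 11538 genes modelled on IM-9 at 24 h, the fit recovered 53.7% of genes changed by 0.25, 92.5% of those changed by 0.5 and 98.5% of those changed by 1 on the log2 scale. The corresponding shares modelled on U266 at 1 h were 64.2%, 98.5% and 100%. Among genes simulated without a change, 10 and 5 were called. With a shift of 0.3 simulated in the p53 targets, camera called that list and 0 others. The simulated noise was independent between genes and held no difference in array brightness. The simulation therefore cannot show false calls that come from correlated genes or from differences between arrays.

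Alternatives fixed in advance were no background correction, scaling to equal medians in place of quantile normalization, the series table as source, no filter on dim probes, detection on all 39 arrays, every kept probe, each line fitted by itself, replicate number as a block, an estimated correlation for the lists, and leaving out each array of the groups compared. Added after the data were seen were array brightness as a covariate, the set of arrays with a highest signal above 60000 as a block, a comparison within that set at 9 h in U266, crossed pairing of replicates in IM-9 at 24 h, list tests under further scalings, and lists on the controls. A block by chip barcode was not run, since no barcode is given.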

Results

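Gene expression was measured in IM-9, a B-lymphoblastoid line transformed by Epstein-Barr virus, and in U266, a multiple myeloma line. Both were exposed to ch128.1Av, an antibody-avidin fusion protein that binds transferrin receptor 1, the cell's main route of iron uptake. IM-9 was sensitive and U266 tolerant to it. The comparisons ask which genes respond to ch128.1Av over 24 h in each line and whether the responses differ. There were 39 arrays, 19 of IM-9 and 20 of U266. Each line had 2 untreated arrays at 0 h and 2 buffer arrays at 1, 3, 9 and 24 h. The treated groups held 2 arrays, or 3 at 3 h in IM-9 and at 1 and 9 h in U266. Each change below is a log2 difference in normalized intensity with its standard error (SE) and the limma adjusted p, over 11538 genes tested.

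Per array, the median raw intensity ran from 137.9 to 223.3 and 8967 to 10067 probes were detected. The lowest correlation between replicates of a group was 0.994, across genes, which are not independent replicates. Array brightness, the ratio of the 75th to the 5th percentile of raw intensity, differed between some treated and control groups. In IM-9 at 24 h it was 9.24 and 9.29 on the control arrays and 3.97 and 6.71 on the treated ones. In U266 at 1 h it was 8.89 and 9.21 on the controls and 3.96 to 5.62 on the treated arrays. The highest raw signal was 61365.4 to 67436.7 on 7 U266 arrays, namely both controls at 9 h, all treated arrays at 1 h, treated replicate 2 at 3 h and treated replicate 1 at 9 h. On the remaining 32 arrays it was 41092.3 to 58405.

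**Figure D1:**
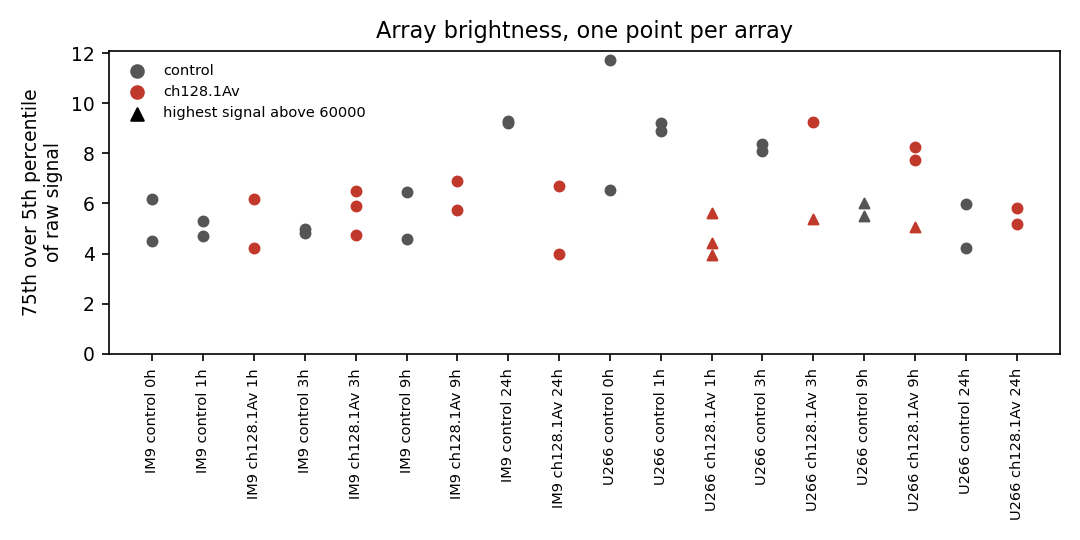
Ratio of the 75th to the 5th percentile of raw signal (unitless) for each of the 39 arrays, by group. Each point is 1 array and triangles are the 7 with a highest signal above 60000; in IM-9 at 24 h controls lie at 9.24 and 9.29 and treated arrays at 3.97 and 6.71.

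The mRNA of TFRC, which encodes the receptor bound by ch128.1Av, was higher with treatment than with buffer in both lines. In IM-9 at 24 h it was 1.5-fold higher than with buffer (0.59, SE 0.0544, n = 2 and 2, adjusted p = 1.59e-07), a call that held under every alternative and without each array. In IM-9 at 9 h it was 1.24-fold higher (0.31, adjusted p = 0.0161). In U266 it was 1.26-fold higher at 9 h (0.33, SE 0.0497, n = 3 and 2, adjusted p = 0.00307) and 1.32-fold higher at 24 h (0.40, SE 0.0544, n = 2 and 2, adjusted p = 0.00167). The difference between the lines did not pass the test at 9 h (-0.02, adjusted p = 0.998) or at 24 h (0.18, SE 0.077, adjusted p = 0.169).

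TFRC was also measured against untreated cells at 0 h in each line, with no test of the difference between the lines in these changes. In U266 the buffer controls were lower than at 0 h, by 0.39 at 9 h (adjusted p = 0.000253) and 0.52 at 24 h (adjusted p = 1.9e-05). Treated cells were at -0.06 (adjusted p = 0.733) and -0.12 (adjusted p = 0.218). Both controls at 9 h, but neither at 0 h, belonged to the 7 arrays with the highest top signal. Hour and array set therefore cannot be told apart in the 9 h change. Of 13 calls of eligible genes in the U266 controls at 24 h, TFRC among them, 0 held under every processing alternative fixed in advance. In IM-9 treated cells rose by 0.29 at 9 h (adjusted p = 0.00147) and 0.41 at 24 h (adjusted p = 6.07e-06), while controls at 24 h were at -0.18 (adjusted p = 0.0286), a call lost without replicate 1 at 0 h (adjusted p = 0.339) or replicate 1 (0.149) or 2 (0.0719) at 24 h. The earlier changes against buffer did not pass: 0.09 and 0.15 at 1 and 3 h in IM-9 (adjusted p = 1 and 0.828), and -0.03 and 0.03 in U266 (adjusted p = 0.77 and 1), the U266 values turning to 0.11 and -0.29 when arrays were scaled to equal medians. The call in IM-9 at 9 h was lost without control replicate 2 (adjusted p = 0.315) or treated replicate 1 (0.172) or 2 (0.182). In U266 the call at 9 h was lost without control replicate 1 (0.127) or 2 (0.0948), and that at 24 h without control replicate 1 (0.0747) or treated replicate 2 (0.127). For the TFRC calls in IM-9 at 9 h and in U266 at 9 and 24 h, median scaling raised the adjusted p to 0.934, 0.461 and 1, and a fit of each line by itself to 0.152, 0.0852 and 0.0803. At 9 h both U266 controls but only 1 of 3 treated arrays belonged to the 7 with the highest top signal, and with that set as a block TFRC was at 0.30 and not called (adjusted p = 0.214). Within the set, with 1 treated array against 2 controls, it was at 0.33.

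**Figure D2:**
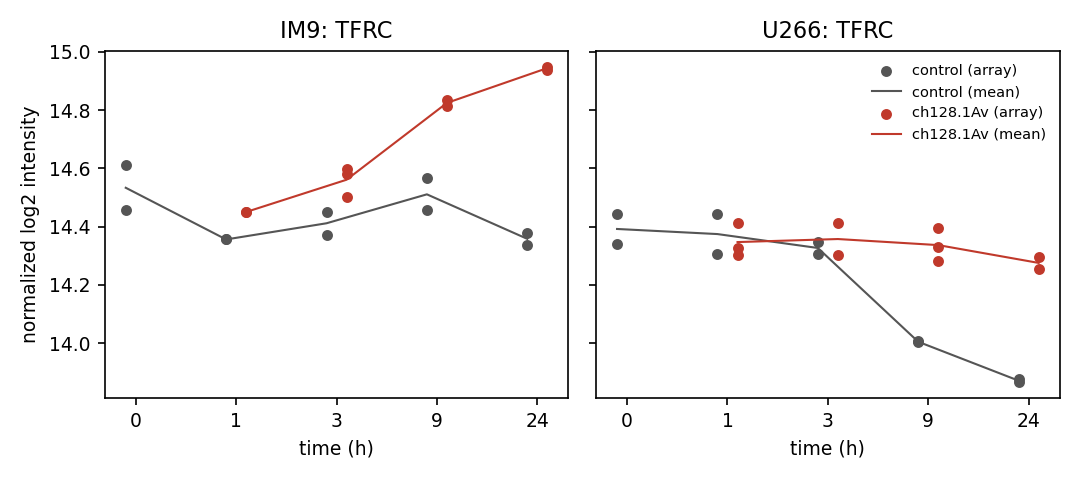
Normalized log2 intensity of TFRC against hours (0, 1, 3, 9 and 24, evenly spaced) in each line, with a point per array and a line through group means for buffer and ch128.1Av. At 24 h the means are 14.94 with ch128.1Av and 14.36 with buffer in IM-9, and 14.28 and 13.87 in U266.

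Before treatment the lines differed in most genes. SEPTIN9, a cytoskeletal GTPase, was 127.9-fold higher in IM-9 (SE 0.0354 on the log2 scale, n = 2 and 2, adjusted p = 8.53e-35). FCER2, the B cell activation antigen CD23, was at least 59.6-fold higher there, and EBI3, a gene induced by Epstein-Barr virus, at least 68.2-fold. MYC, the growth transcription factor, was 18.6-fold higher (adjusted p = 3.84e-26). CCND1, the cyclin D1 gene often overexpressed in myeloma, was at least 142-fold higher in U266 (adjusted p = 9.73e-33), QPCT at least 189-fold, and CCL3L1, a chemokine, 50.1-fold. In all, limma called 3839 genes higher in IM-9 and 3923 higher in U266, of which 1025 and 1016 differed at least 2-fold.

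By list at 0 h, B cell identity genes were higher in IM-9 (18 higher and 2 lower of 21, camera adjusted p = 2.36e-07, median 1.60). Plasma cell identity genes were lower in IM-9 (6 higher and 13 lower of 20, adjusted p = 0.0107, and adjusted p = 0.0677 with an estimated correlation). Amino acid and stress genes driven by ATF4 were lower in IM-9 (1 higher and 24 lower of 27, adjusted p = 6e-05), with DDIT3 at -2.34. MYC and ribosome biogenesis genes (20 higher and 2 lower of 27, adjusted p = 0.000247), NF-kB targets (16 and 2 of 23, adjusted p = 0.000108) and p53 targets (16 and 4 of 23, adjusted p = 0.00425) were higher in IM-9, with CDKN1A at 1.88, although its probe did not pass detection on either U266 array at 0 h, where its level was 10.86. Interferon-stimulated genes were lower in IM-9 (3 higher and 12 lower of 20, adjusted p = 0.0114, and adjusted p = 0.247 with an estimated correlation). The counts adjusted over the list alone were the same for these lists, except 20 and 3 for MYC and ribosome biogenesis. The other 13 lists did not pass (adjusted p from 0.364 to 0.966), and among them the median and the mean differed in sign for the unfolded protein response (0.38 and -0.19), immediate early genes (-0.03 and 0.26) and cholesterol biosynthesis (0.05 and -0.02). TFRC itself was 0.14 higher in IM-9 (adjusted p = 0.0252), a call lost without replicate 1 of IM-9 (adjusted p = 0.385) or replicate 2 of U266 (0.238).

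In buffer alone, many genes differed between 0 and 24 h in both lines. In IM-9 the glycolytic regulator PFKFB4 rose 9.01-fold (3.17, SE 0.223, n = 2 and 2, adjusted p = 8.19e-10), and other genes that respond to low oxygen rose, such as ALDOC by 2.03, BNIP3L by 1.93, ANKRD37 by 1.64 and BNIP3 by 1.37. ID3, a transcription regulator, was 4.35-fold lower (-2.12, SE 0.12, adjusted p = 1.41e-11). In U266 AHNAK rose by 0.94 (SE 0.17, adjusted p = 0.00135) and MCM6, a replicative helicase subunit, fell by 0.76 (SE 0.109, adjusted p = 0.000212). The limma calls were 1034 risen and 832 fallen genes in IM-9 and 648 and 811 in U266. Scaling to equal medians moved the median of all genes in IM-9 to 0.132 and gave 1070 risen and 31 fallen genes there and 4 and 2 in U266, with AHNAK at an adjusted p of 0.269 and MCM6 at 0.246. Without control replicate 2 at 24 h IM-9 had 1151 calls, and U266 had 288 without replicate 1 at 0 h and 222 without replicate 1 at 24 h. Array brightness also differed, at 4.52 and 6.17 at 0 h against 9.24 and 9.29 at 24 h in IM-9 and at 6.55 and 11.7 against 4.23 and 5.99 in U266. The 5th percentile of raw intensity was 137.5 and 140.5 at 0 h against 106 and 107.4 at 24 h in IM-9. In U266 it was 92 and 108.5 against 118 and 130.4. Hour therefore went together with a difference between arrays, and how much of these counts reflects it is not settled. With brightness as a covariate 1517 genes were called in IM-9, 1094 of them among the 1866, and 322 in U266, 289 of them among the 1459.

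In IM-9 few genes answered ch128.1Av before 24 h. At 1 h limma called 0 genes, with 236 at an unadjusted p under 0.05, and no list passed camera (smallest adjusted p = 0.911). At 3 h BCAR3, a signalling adaptor, rose by 0.22 (SE 0.0341, n = 3 and 2, adjusted p = 0.0122), and ZBTB32, a repressor in B cells, fell by 0.21 (SE 0.0332, adjusted p = 0.0126). At 9 h 5 genes rose and 5 fell, with 1005 at an unadjusted p under 0.05. The prostaglandin receptor gene PTGER4 rose by 0.37 (SE 0.0542, n = 2 and 2, adjusted p = 0.00336), FSTL3 by 0.33 (adjusted p = 0.00367) and TFRC by 0.31, while SP140 fell by 0.26 (adjusted p = 0.00339) and FCRLA, a B cell gene, by 0.43 (adjusted p = 0.0217).

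Cholesterol biosynthesis genes were called higher in IM-9 at 3 h (median 0.04, 0 of 17 past the threshold over all genes and 1 adjusted over the list alone, adjusted p = 0.0327, and adjusted p = 0.0549 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.274) and treated replicates 2 (0.0855) and 3 (0.152). At 9 h G2/M and mitosis genes were called lower (median -0.07, 0 of 30 and 1 over the list alone, adjusted p = 0.0079), a median that turned to 0.10 under equal medians (adjusted p = 0.458). Hypoxia genes were called higher at 9 h (median 0.07, 0 of 35 and 2 over the list alone, adjusted p = 0.00812, and adjusted p = 0.44 with an estimated correlation). Without control replicate 1 neither list was called (adjusted p = 0.19 for each). No gene called at 3 or 9 h kept its call through each omission of an array: the 3 h count was 0 when control replicate 1, control replicate 2 or treated replicate 1 was left out and 1 when treated replicate 2 or 3 was. The 9 h count was 0 without either treated replicate and 18 without control replicate 1. With equal medians it was 0 at both hours, and the median of all genes at 1 h moved to 0.113.

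At 24 h many genes were called in IM-9, led by genes that p53 activates, though the number called depended on the arrays and the processing. TP53I3, a p53-induced oxidoreductase, was 3.16-fold higher than with buffer (1.66, SE 0.101, n = 2 and 2, adjusted p = 8.64e-11). The growth arrest and DNA repair genes GADD45A (2.21-fold, 1.14, SE 0.123, adjusted p = 1.25e-06) and DDB2 (2.13-fold, 1.09, SE 0.121, adjusted p = 2.18e-06) rose, as did PHLDA3, an AKT inhibitor (2.12-fold, 1.08, SE 0.0818, adjusted p = 4.75e-09). CDKN1A, the cell cycle inhibitor p21, rose 1.92-fold (0.94, SE 0.0847, adjusted p = 9.37e-08). Outside that list APOBEC3G, a cytidine deaminase, rose 1.99-fold (0.99, SE 0.0526, adjusted p = 1.66e-11), DHRS3 1.95-fold and the chemokine gene CCL3L3 2.15-fold. Among fallen genes were RRP15, which acts in ribosome assembly (1.79-fold lower, adjusted p = 0.00016), the heat shock gene HSPA1B (1.77-fold lower, -0.82, SE 0.0795, adjusted p = 2.52e-07) and NAA15 (1.76-fold lower, adjusted p = 5.18e-06). Each of these calls held without each of the 4 arrays in turn and under every processing alternative tried. Other called genes eligible to be named were less stable, and CHORDC1, COMMD2, CUTC, HNRNPF and KCTD9, all lower, lost their calls without an array. Of the 83 calls of eligible genes, 29 held under every processing alternative fixed in advance and 52 with array brightness as a covariate.

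Of the 23 measured p53 targets, 18 rose and 0 fell in IM-9 at 24 h (19 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 2.13e-21, and adjusted p = 9.09e-09 with an estimated correlation). BBC3, the pro-apoptotic gene PUMA, did not pass (0.06, SE 0.066, adjusted p = 0.656, and -0.10 under equal medians). In U266 at 24 h 0 of the 23 passed (adjusted p = 0.494, median 0.01), with TP53I3 at -0.28, GADD45A at -0.10, CDKN1A at 0.20 and BBC3 at -0.05. Some members were low and flat on all U266 arrays, such as PHLDA3 (7.68 to 7.80) and MDM2 (7.74 to 7.82). PHLDA3 was at 8.98 and 9.16 on the IM-9 controls at 24 h. TP53I3 was not low in U266, at 9.91 and 9.82 on the controls at 24 h. Whether the low members could show a response in U266 is not known. The list's difference between lines passed (adjusted p = 1.75e-15). Under equal medians the median of the list in IM-9 was 0.105, against -0.148 for all genes, and the list stayed called (adjusted p = 3.33e-14).

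**Figure D3:**
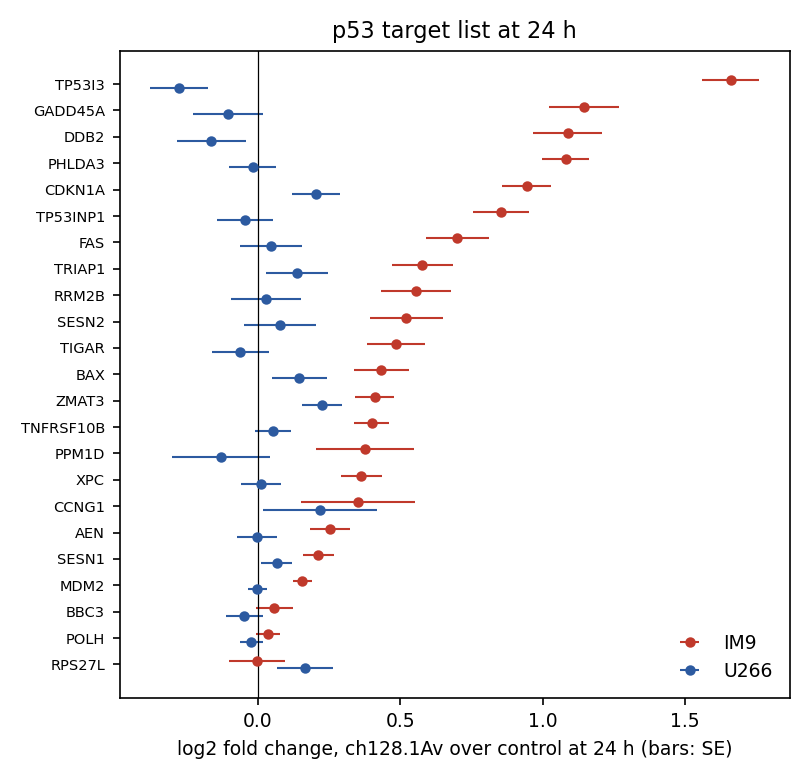
Log2 fold change (ch128.1Av against buffer) at 24 h of the 23 measured p53 targets in IM-9 and U266, with points for the fitted value and bars for 1 SE. TP53I3 is at 1.66 in IM-9 and -0.28 in U266, and under equal medians the list's median in IM-9 is 0.105 against -0.148 for all genes.

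Mitotic genes were lower in IM-9 at 24 h: 0 of 30 G2/M genes rose and 13 fell (16 adjusted over the list alone, adjusted p = 1.26e-06, and 0.000256 with an estimated correlation), with the kinase AURKA at -0.44 (SE 0.0561, adjusted p = 1.11e-05) and the mitotic activator CDC20 at -0.42 (SE 0.071, adjusted p = 0.000333). The proliferation marker MKI67 was at -0.00 (adjusted p = 0.995). Of 19 heat shock genes 9 fell and 0 rose (10 and 0 over the list alone, adjusted p = 3.09e-05, and 0.00189 with an estimated correlation), with HSPA1B and the co-chaperone DNAJB1 (-0.58, SE 0.0626, adjusted p = 1.26e-06). MYC and ribosome biogenesis genes were lower (1 risen and 7 fallen of 27, 1 and 10 over the list alone, adjusted p = 0.0232, and 0.0576 with an estimated correlation), with WDR12 at -0.32 and MYC itself at 0.04 (adjusted p = 0.767, and -0.26 under equal medians). Hypoxia genes were higher (10 risen and 1 fallen of 35, 11 and 1 over the list alone, adjusted p = 0.000327, and adjusted p = 0.171 with an estimated correlation), with P4HA1 at 0.82, PFKFB3 at 0.71 and ALDOC at 0.60, 3 calls that were lost under equal medians, as was WDR12 (adjusted p = 0.292, 0.134, 0.469 and 0.0728). Of the hypoxia genes always followed, BNIP3 was at 0.36 to 0.62 with any 1 array left out, and its call depended on single arrays. NDRG1 turned negative without control replicate 2 (-0.018) or treated replicate 1 (-0.042). The treated arrays were the dimmer ones in this comparison, at 3.97 and 6.71 against 9.24 and 9.29 on the brightness ratio.

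NF-kB targets were called higher in IM-9 at 24 h (5 risen and 1 fallen of 23, 6 and 2 over the list alone, adjusted p = 0.0232, and adjusted p = 0.13 with an estimated correlation), with the chemokine CCL3 at 0.82 and CFLAR, an inhibitor of caspase activation, at 0.53. Plasma cell identity genes (7 risen and 0 fallen of 20 on each count, adjusted p = 0.0232, and adjusted p = 0.12 with an estimated correlation) included PRDM1 at 0.80 and IRF4 at 0.59, transcription factors of plasma cell differentiation. Interferon-stimulated genes (5 risen and 0 fallen of 20 on each count, adjusted p = 0.025, and adjusted p = 0.307 with an estimated correlation) included HERC5 at 0.55 and IFI35 at 0.51. Under equal medians the median of the NF-kB list turned to -0.17 (adjusted p = 0.926), those of the hypoxia and interferon lists to -0.01, with both lists still called, and the plasma cell and heat shock calls were lost (adjusted p = 0.108 for each). The calls of CCL3, CFLAR, PRDM1, IRF4, HERC5 and IFI35 were lost there as well (adjusted p from 0.159 to 0.869).

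Single arrays decided some of these list calls in IM-9 at 24 h. Without control replicate 1 the adjusted p was 0.0686 for NF-kB targets and for plasma cell identity and 0.085 for MYC and ribosome biogenesis. Without treated replicate 1 it was 0.122 for MYC and ribosome biogenesis, 0.0964 for plasma cell identity and for hypoxia, and 0.18 for interferon-stimulated genes, and without treated replicate 2 it was 0.257 for NF-kB targets. The p53, G2/M and heat shock lists stayed called without each array, with adjusted p up to 1.19e-13, 0.000447 and 0.00862.

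No other list passed in IM-9 at 24 h. Iron genes had 2 risen and 2 fallen of 17 (adjusted p = 0.962), among them TFRC and FTL, the ferritin light chain (-0.30, SE 0.041, adjusted p = 2.7e-05, and 0.605 under equal medians). G1/S and DNA replication had 6 risen and 3 fallen of 33 (adjusted p = 0.109), ATF4 targets 4 and 1 of 27 (0.153), with DDIT3 at 0.23 (adjusted p = 0.0802), and the unfolded protein response 3 and 1 of 21 (0.273), with HSPA5 at -0.58. The BCL2 family and caspases had 2 and 0 of 25 (0.29), immediate early genes 2 and 0 of 20 (0.115), cholesterol biosynthesis 1 and 1 of 17 (0.8), respiratory chain subunits 1 and 3 of 32 (0.402), iron-sulfur cluster and heme synthesis 1 and 3 of 22 (0.8), and NRF2 and metallothionein genes 1 and 4 of 20 (0.431). B cell identity had 4 and 2 of 21 (0.962), and markers of T, NK, myeloid, erythroid, epithelial and stromal cells 1 and 1 of 10 (0.899). Counts adjusted over the list alone differed for iron genes (4 and 3), G1/S (8 and 4), the unfolded protein response (5 and 2) and B cell identity (4 and 4). The median was negative and the camera direction up for the iron (-0.04), cholesterol (-0.02), iron-sulfur (-0.01) and B cell (-0.03) lists, with the mean also negative for the last 2.

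In total limma called 710 risen and 834 fallen genes in IM-9 at 24 h (3059 at an unadjusted p under 0.05), of which 6 rose at least 2-fold and 0 fell as much. The count of 1544 was 545 without control replicate 2, 2338 without treated replicate 1 and 399 without treated replicate 2. Under equal medians 61 rose and 687 fell, and with array brightness as a covariate 631 were called, 537 of them among the 1544. The treated arrays had the lower brightness ratio here, as they had in U266 at 1 h. Their median raw intensity was lower than on the controls here, but higher in U266 at 1 h. Over the genes called in U266 at 1 h, the change there correlated with that in IM-9 at 24 h at r = 0.611, genes not being independent replicates. How much of the count of 1544 reflects a difference between arrays is not settled.

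In U266 the comparison at 1 h gave many calls with no gene list among them. CPEB4, a regulator of mRNA translation, was 2.21-fold higher than with buffer (1.14, SE 0.14, n = 3 and 2, adjusted p = 8.44e-05). FDPS, an enzyme of the mevalonate pathway, rose by 0.79 (SE 0.116, adjusted p = 0.000834), the nucleolar gene NCL by 0.77 (SE 0.124, adjusted p = 0.00147) and CAV1 by 0.59 (SE 0.103, adjusted p = 0.00224). The replication gene MCM2 was 1.46-fold lower (adjusted p = 0.00157), the interferon-stimulated IFIT2 1.41-fold lower (adjusted p = 0.00109) and SESN1, a p53 target, 1.22-fold lower (adjusted p = 0.00224). These calls held without each of the 5 arrays, which most of the 60 calls of genes eligible to be named at this hour did not. With array brightness as a covariate 8 of the 60 held. The largest changes were in CDC14B (6.02-fold, SE 0.548, adjusted p = 0.00761) and ACTG1 (5.93-fold, SE 0.749, adjusted p = 0.0349), which were lost without control replicate 1 (adjusted p = 0.0833 and 0.407), ACTG1 also without treated replicate 1 (0.0588) or 2 (0.105).

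In all, 518 genes rose and 512 fell in U266 at 1 h (3079 at an unadjusted p under 0.05), while each of the 20 lists had a camera adjusted p of 0.934 to 0.988. Their medians lay between -0.05 and 0.04 and differed in sign from the mean or the camera direction in some, such as ATF4 targets (median -0.03, mean 0.09). Of the 23 p53 targets 0 rose and 2 fell on each count. The treated arrays had a lower brightness ratio than the controls, at 3.96 to 5.62 against 8.89 and 9.21. Their median raw intensity was higher, however, at 190.8 to 216.6 against 169.3 and 170.7. All 3 treated arrays belonged to the 7 with the highest top signal. Against these 1030 calls, limma called 60 genes under equal medians (56 risen and 4 fallen), 205 with U266 fitted by itself, 41 with array brightness as a covariate, 38 of them among the 1030, and 2 with the set of 7 arrays as a block, in which CPEB4 had an adjusted p of 0.114. Of the genes named for this hour, CPEB4 was the only one called under all processing alternatives fixed in advance. The count was 212 without control replicate 1, 527 without control replicate 2 and 318 without treated replicate 2.

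At 9 h in U266 a pair of sterol genes moved in opposite directions. INSIG1, which restrains sterol synthesis and is itself induced when sterols are low, was 1.77-fold higher (0.82, SE 0.12, n = 3 and 2, adjusted p = 0.00285), and ABCA1, the cholesterol exporter, was 1.5-fold lower (-0.59, SE 0.0679, adjusted p = 0.000127). IKZF1, a lymphoid transcription factor, fell by 0.59 (SE 0.0931, adjusted p = 0.00497). Cholesterol biosynthesis genes were called higher as a list (1 risen and 0 fallen of 17 on each count, median 0.06, adjusted p = 0.000623, and 0.00406 with an estimated correlation), a call that held without each array (adjusted p up to 0.0437), and no other list was called. In total 3 genes rose and 2 fell, with 414 at an unadjusted p under 0.05. ABCA1 stayed called without each array, while INSIG1 and IKZF1 were lost without control replicate 1 (adjusted p = 0.127 for each) or 2 (0.0667 and 0.269), and IKZF1 without treated replicate 3 (0.0644). Both controls but only 1 of 3 treated arrays belonged to the 7 with the highest top signal: with that set as a block ABCA1 stayed called (-0.66, adjusted p = 0.000269), while INSIG1 (0.76, adjusted p = 0.183) and IKZF1 (-0.40, adjusted p = 0.499) did not. Within the set, with 1 treated array against 2 controls, ABCA1 was at -0.69, INSIG1 at 0.73 and IKZF1 at -0.49. Under equal medians, which moved the median of all genes to 0.163, limma called 0 genes, and the count was 1 without either control, 10 without treated replicate 1 and 3 without treated replicate 3.

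At 3 h in U266 ANKRD20A3P, a pseudogene, fell by 0.45 (SE 0.0692, n = 2 and 2, adjusted p = 0.0138) as the only call, with 551 genes at an unadjusted p under 0.05 and no list past the threshold (smallest adjusted p = 0.807). It was lost without control replicate 1 (adjusted p = 1) or treated replicate 1 (0.0765), and without treated replicate 2 the count was 48. Under equal medians the median of all genes moved to -0.229 and 11 genes fell.

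At 24 h in U266 TFRC was higher than with buffer, where the controls were lower than at 0 h in the main fit. TJP1, a tight junction gene, was 0.35 lower than with buffer (SE 0.0595, n = 2 and 2, adjusted p = 0.0251), with 817 genes at an unadjusted p under 0.05. Several lists shifted although 0 of their members passed over all genes. Cholesterol biosynthesis genes were called higher (median 0.11, 3 of 17 adjusted over the list alone, adjusted p = 1.83e-05, and 0.000861 with an estimated correlation), with INSIG1 at 0.53 (adjusted p = 0.203). Hypoxia genes were called higher (median 0.13, 6 of 35 over the list alone, adjusted p = 2.52e-06, and adjusted p = 0.0774 with an estimated correlation), with BNIP3 at 0.54 (adjusted p = 0.273) and PFKFB4 at 0.92 (adjusted p = 0.2). Immediate early genes (median -0.02, 4 of 20 lower over the list alone, adjusted p = 0.00354) and NF-kB targets (median -0.01, 3 of 23 lower, adjusted p = 0.0167) were called lower, with KLF6 at -0.72 and TNFAIP3 at -0.48, a pair chosen after their values were seen. Their adjusted p values were 0.0774 and 0.108 with an estimated correlation.

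Replication genes (G1/S, median 0.07, adjusted p = 0.00231), unfolded protein response genes (median 0.08, adjusted p = 0.0111) and plasma cell identity genes (median 0.07, adjusted p = 0.00517) were called higher in U266 at 24 h with 0 members past the threshold on either count. Their adjusted p values were 0.148, 0.0774 and 0.0774 with an estimated correlation, and under equal medians, which put the median of all genes at -0.0396, these 3 medians were -0.01, -0.02 and -0.02 and all 3 calls were lost. Without control replicate 1 the adjusted p was 0.392 for hypoxia, 0.767 for the unfolded protein response and 0.608 for G1/S, plasma cell identity, NF-kB targets and immediate early genes, while cholesterol biosynthesis stayed called without each array (up to 0.00376). The other 13 lists were not called in U266 at 24 h (adjusted p from 0.343 to 0.781). The unfolded protein response was also lost without treated replicate 1 (0.0526) and NF-kB without treated replicate 2 (0.109). The TJP1 call was lost without control replicate 1 (0.72) or treated replicates 1 (0.0697) and 2 (0.58), and the count of 2 became 0 without control replicate 1 or treated replicate 2, 1 without treated replicate 1 and 415 without control replicate 2.

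**Figure D4:**
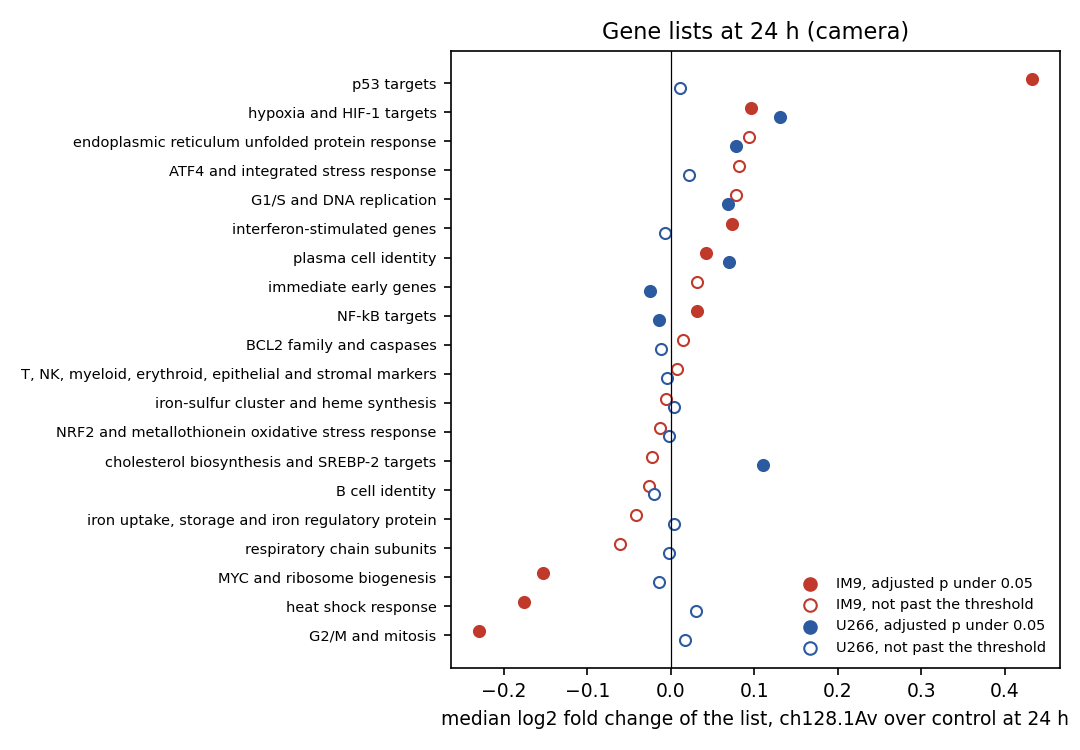
Median log2 fold change (ch128.1Av against buffer) of each of the 20 gene lists at 24 h in IM-9 and U266, with a filled point where camera's adjusted p is under 0.05. The p53 targets are at 0.43 in IM-9 and 0.01 in U266; under equal medians the NF-kB, hypoxia and interferon medians in IM-9 turn to -0.17, -0.01 and -0.01, and the G1/S, unfolded protein and plasma cell medians in U266 to -0.01, -0.02 and -0.02, against -0.148 and -0.0396 for all genes in IM-9 and U266.

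By list, the test of the difference between the lines at 24 h was led by p53 targets and mitotic genes. TP53I3 differed by 1.94 (SE 0.143, adjusted p = 1.55e-08), DDB2 and GADD45A by 1.25 each (adjusted p = 0.000129 and 0.000151) and CDKN1A by 0.74 (adjusted p = 0.000699). TXNIP, a negative regulator of thioredoxin, differed by 1.45 (SE 0.292, adjusted p = 0.00532), with 0.55 in IM-9 (adjusted p = 0.0801) and -0.90 in U266 (adjusted p = 0.18). HSPA1B differed by -0.87 (SE 0.112, adjusted p = 7.24e-05). Of the p53 targets 10 differed positively and 0 negatively (15 and 0 over the list alone, adjusted p = 1.75e-15, and 1.63e-07 with an estimated correlation). Of the G2/M genes 0 and 5 did (0 and 10, adjusted p = 3.8e-06, and 0.000417), with AURKA at -0.43, and of the heat shock genes 0 and 3 (0 and 6, adjusted p = 9.95e-05, and 0.00334). In all, 562 genes differed, 275 positively and 287 negatively.

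The count of differing genes at 24 h depended on single arrays. It was 190 without control replicate 2 of IM-9, 186 and 1623 without treated replicates 2 and 1 of IM-9, 234 without control replicate 1, 847 without control replicate 2, and 241 and 249 without treated replicates 1 and 2 of U266. Under equal medians 12 genes differed, and the p53 (adjusted p = 6.31e-10) and G2/M (0.00165) lists stayed called, while the heat shock list (0.121), TP53I3 (0.0511), GADD45A (0.0547), DDB2 (0.0681), TXNIP (0.144) and HSPA1B (0.155) did not. At 1, 3 and 9 h, limma called 10, 0 and 2 differing genes, with 1578, 334 and 446 at an unadjusted p under 0.05, and under equal medians 0 at each hour, with the median of all genes at 0.142 and 0.275 at 1 and 3 h. No list differed at 1 or 3 h (smallest adjusted p = 0.791 and 0.462). ABCA1 differed at 9 h (0.61, SE 0.101, adjusted p = 0.0378), with 0.03 in IM-9 and -0.59 in U266, a call lost without either control (adjusted p = 0.126 and 0.0592) or treated array (0.271 and 0.192) of IM-9 and without control replicates 1 and 2 (0.0934 and 0.324) or treated replicates 1 and 2 (0.0919 and 0.069) of U266.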

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

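Among the tests in this part, those of array brightness and of its slope between replicates on the 1 h calls in U266, and that of a response of IM-9 that U266 lacks, were chosen only after the result was seen, as were the array brightness covariate and the block of 7 arrays themselves, the need for calls to remain with that block in the test of a response at 1 h, and the need for both correlations to be low in the test of the set of 7 arrays.

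The effect of ch128.1Av differed between the lines in 10 genes at 1 h, 2 at 9 h and 562 at 24 h by the test of the difference itself (IM-9 minus U266). At 1 h the differences were -1.13 in CPEB4, -0.88 in IL12B, -0.73 in ANAPC7, -0.70 in GNL3L and -0.66 in SLC25A47, and each of these calls was lost without any of the 4 IM-9 arrays of that hour (adjusted p from 0.0677 to 0.213) and without control replicate 1 of U266 (0.15 to 0.252). CPEB4 was also lost without treated replicates 1 (0.0601) and 2 (0.094) of U266, and ANAPC7 without treated replicate 2 (0.109). At 9 h the difference was 0.61 in ABCA1, lost without any 1 of the arrays compared (adjusted p from 0.0592 to 0.324) except treated replicate 3 of U266. At 24 h it was 1.94 in TP53I3, 1.53 in PLEKHF1, 1.45 in TXNIP, 1.25 in DDB2 and 1.25 in GADD45A, and -0.98 in KIF15, -0.93 in CCNF, -0.87 in ENOPH1, -0.87 in CUTC and -0.87 in HSPA1B. Without control replicate 2 of IM-9 the adjusted p was 0.0516 for PLEKHF1, 0.14 for KIF15, 0.0797 for CCNF, 0.0578 for ENOPH1 and 0.164 for CUTC. Without treated replicate 2 of IM-9 it was 0.212 for KIF15, 0.0842 for CCNF, 0.0748 for ENOPH1 and 0.202 for CUTC. Without control replicate 1 of U266 it was 0.0509 for PLEKHF1, 0.116 for KIF15, 0.0611 for ENOPH1 and 0.0945 for CUTC, and without treated replicates 1 and 2 of U266 it was 0.0718 and 0.0687 for KIF15 and 0.0618 and 0.0735 for CUTC.

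By list the difference between lines at 9 h passed for hypoxia genes (higher in IM-9, adjusted p = 0.00223, and adjusted p = 0.271 with an estimated correlation), and for G2/M (adjusted p = 0.0217, 0.102), cholesterol biosynthesis (0.00377, 0.0195), NRF2 and metallothionein (0.018, 0.124) and interferon-stimulated genes (0.0136, 0.271), all lower in IM-9. At 24 h it passed for p53 targets (1.75e-15, 1.63e-07), NF-kB targets (0.00114, 0.0294), immediate early genes (0.00375, 0.0785) and interferon-stimulated genes (0.0142, 0.218), all higher in IM-9, and for G2/M (3.8e-06, 0.000417) and heat shock genes (9.95e-05, 0.00334), lower in IM-9. Under equal medians NF-kB targets (0.775), immediate early genes (0.0914) and heat shock genes (0.121) lost the call at 24 h, and NRF2 and metallothionein genes (0.086) at 9 h.

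Single arrays decided several of these list differences. At 9 h G2/M was lost without control replicate 1 (adjusted p = 0.339) or treated replicate 2 (0.1) of IM-9 and control replicate 2 (0.209) or treated replicate 1 (0.0564) of U266, hypoxia without treated replicate 1 of U266 (0.0564), NRF2 and metallothionein without control replicate 2 (0.0923) or treated replicate 2 (0.0793) of IM-9 and control replicate 2 of U266 (0.209), and interferon-stimulated genes without control replicate 2 of IM-9 (0.45) and control replicate 1 (0.511) or treated replicate 3 (0.104) of U266. At 24 h immediate early genes were lost without control replicate 1 of U266 (0.0586) and interferon-stimulated genes without treated replicate 1 of IM-9 (0.125) or treated replicate 2 of U266 (0.139).

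The rise of p53 targets in IM-9 at 24 h came with treated arrays that were dimmer than the controls. With array brightness as a covariate the median of the list was 0.479, against 0.43 without it, and with either treated array left out it was at least 0.394, which argues against brightness or a single treated array as the whole cause. The test of the difference between the lines passed for this list (adjusted p = 1.75e-15), in line with a response of IM-9 that U266 lacks. Members that were low in U266 at every hour, such as PHLDA3, limit that comparison. A difference between the treated and control cultures other than the drug stays open, as does the reason why the lines differ, since the labels name 1 sensitive and 1 tolerant line and no others.

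The 1030 calls in U266 at 1 h, at an hour with no called list, may be in large part a difference between arrays. With brightness as a covariate 41 were called, 38 of them among the 1030, as the median change of the called genes, signed by their direction, went from 0.286 to 0.179 while the median SE went from 0.0734 to 0.081. Over the called genes the change correlated with the slope on brightness between replicates of the other groups at r = -0.714, genes not being independent replicates. The set of 7 arrays with a high top signal stays open, since the called genes' difference between replicates correlated with the change at r = 0.897 within the treated 3 h group and at -0.255 within the treated 9 h group, each resting on 1 array of the set. A response at 1 h cannot be told apart from a difference between arrays: with the set as a block 2 genes were called, and the signed median of 0.183 (median SE 0.0998) is positive by selection, its genes being chosen and signed by this same comparison.

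Hypoxia genes were called higher with ch128.1Av than with buffer at 24 h in both lines, though not with an estimated correlation. From 0 to 24 h the controls' own median for the list had moved by 0.264 in IM-9 and by 0.00599 in U266. With brightness as a covariate the median of the list in IM-9 went from 0.0968 to 0.186, which argues against brightness as the whole cause there. In U266 it went from 0.131 to 0.119. The treated (5.19 and 5.83) and control arrays (4.23 and 5.99) of U266 overlapped in brightness, so the covariate could change little in that line. A further advance of the change seen in the controls cannot be told apart from an effect of the drug: over the genes of the list the change with the drug correlated with the controls' change at 0.00557 in IM-9 and 0.148 in U266. The controls at 24 h enter both changes, which in simulated groups with no change gave a mean r of -0.49 (central range -0.819 to -0.0239). That simulation left out the controls' own change, whose mean over the list was 0.497 in IM-9 and 0.11 in U266. How far the shared controls lower r in these data is therefore not known, and the simulation decides nothing. The lower observed value was under the bound set beforehand against a shared advance, a bound that made no allowance for the shared controls. Neither value reached the correlation set beforehand for a shared advance, which stays open.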

How the results depend on the processing

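Among the alternatives below, the array brightness covariate, the block of arrays with a high top signal, the comparison within those arrays, the crossed pairing and the list tests under other scalings were chosen only after the data were seen.

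Over all alternatives 119 of 229 counts stayed within 1.5 times the value reported and 110 moved, 2589 of 3503 values of named genes kept direction and side of the threshold, with 882 weaker, 4 stronger and 28 reversed, and 379 of 458 list tests did so, with 77 weaker and 2 reversed. With no filter on dim probes or with every kept probe all 15 counts stayed within 1.5 times, as did crossed pairing in IM-9 at 24 h (1809). Of the 37 list calls 35 held with no background correction, 35 with the series table, 23 under equal medians, 36 with a replicate block, 36 with brightness, 34 with the top signal block and 16 with an estimated correlation. Newly called among the 260 list tests were 20 under equal medians, 3 with brightness, 1 with no background correction, 1 with the series table and 0 with the other settings. A block by chip barcode was not run, since no barcode is given. Genes near background limit the rest, as 8509 of 20589 probes did not pass detection. When 1 array of a pair was left out, the lone array was assumed to vary like the other groups. Except where fewer arrays or fewer genes make the change, the cause was not tested.

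With no background correction the calls were 0 in IM-9 at 3 h and 0 at 9 h, 0 in U266 at 3 h and 1 at 24 h, and 6, 0 and 316 for the difference between lines at 1, 9 and 24 h, and MKI67 in IM-9 at 24 h was at 0.0066. With the series table these were 0, 0, 0, 1, 6, 0 and 300, and MKI67 0.0074.

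Under median scaling, which moved the median SE from 0.0722 to 0.155, the calls in IM-9 were 0 at 3 h, 0 at 9 h and 748 at 24 h, in U266 60, 11, 0 and 0 at 1, 3, 9 and 24 h, for the difference between lines 0, 0 and 12 at 1, 9 and 24 h, and for the controls 1101 in IM-9 and 6 in U266. Reversed were ADGRE5 in IM-9 at 9 h (0.053), in IM-9 at 24 h SARS1 (-0.019), CIITA (-0.083), CCNE1 (-0.023), CXCL10 (-0.0075), POU2AF1 (-0.0049), BBC3 (-0.097) and MYC (-0.26), in U266 SOD1 (0.39), SSR4 (0.16), ATP5F1B (0.47) and TFRC (0.11) at 1 h and TFRC (-0.29) at 3 h, and the NF-kB list in IM-9 at 24 h (adjusted p = 0.926).

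With detection on all arrays, which tests fewer genes, calls were 0 at 3 h and 0 at 9 h in IM-9, 0, 3 and 1 at 3, 9 and 24 h in U266, 2 and 0 for the difference at 1 and 9 h, and 5143 between the lines at 0 h. With each line by itself, which pools fewer arrays, they were 0 and 0 in IM-9 at 3 and 9 h, 205, 0, 0 and 0 in U266 at 1, 3, 9 and 24 h, and 680 in the U266 controls.

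With replicate number as a block, in place of the unblocked fit, calls were 1 and 6 in IM-9 at 3 and 9 h, 2 in U266 at 3 h and 1 for the difference at 9 h. For same-numbered treated and control arrays, the deviations from their group means were correlated. With 2 arrays in both groups the 2 pairs give the same value, since the deviations in such a group mirror each other. Where a group held 3 arrays, the lower value is given. The correlation was 0.293 in U266 at 3 h and 0.0729 at 24 h, and between -0.698 (U266 at 1 h) and -0.0236 (IM-9 at 9 h) in the other contrasts.

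With brightness as a covariate calls were 631 in IM-9 at 24 h, 41 in U266 at 1 h, 2, 5 and 171 for the difference at 1, 9 and 24 h and 322 in the U266 controls, and BBC3 (-0.074), MYC (-0.00936) and NDRG1 (-0.0018) in IM-9 at 24 h and TFRC in U266 at 1 h (0.076) reversed. With the top signal block calls were 2, 0 and 1 in U266 at 1, 3 and 9 h and 0 and 1 for the difference at 1 and 9 h, with TFRC in U266 at 1 h at 0.024. Within the high top signal arrays U266 at 9 h had 2.

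Leaving out 1 array at a time, calls ranged in IM-9 from 0 to 1 at 3 h, 0 to 18 at 9 h and 399 to 2338 at 24 h. In U266 they ranged from 212 to 1031 at 1 h, 0 to 48 at 3 h, 1 to 10 at 9 h and 0 to 415 at 24 h. For the difference between lines they ranged from 0 to 28 at 1 h, 0 to 1 at 3 h, 0 to 4 at 9 h and 186 to 1623 at 24 h, between the lines at 0 h from 7058 to 7206, and in the controls from 1151 to 1440 in IM-9 and 222 to 1717 in U266. In IM-9 at 24 h MKI67 ranged from -0.17 to 0.16, NDRG1 from -0.042 to 0.062 and MYC from -0.012 to 0.091. In U266 TFRC ranged from -0.095 to 0.040 at 1 h and from -0.025 to 0.086 at 3 h, MYC at 24 h from -0.066 to 0.028, and the adjusted p of the G1/S list at 24 h from 2.18e-06 to 0.608.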

Other observations

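All tests in this part, on lists in the controls and against cells at 0 h, were chosen only after the data were seen, and the lists here were not run under other scalings.

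Between 0 and 24 h in buffer alone, hypoxia genes were called higher in IM-9 (16 risen and 3 fallen of 35, median 0.26, adjusted p = 5.66e-10, and adjusted p = 0.0327 with an estimated correlation) and MYC and ribosome biogenesis genes lower (2 risen and 10 fallen of 27, adjusted p = 0.00134, and 0.0158). With calls lost at an estimated correlation, IM-9 controls also had lower G1/S (adjusted p = 0.0152, and 0.289), heat shock (0.0173, and 0.066) and NRF2 and metallothionein genes (0.0359, and 0.145), and higher B cell identity genes (0.0152, and 0.066). In U266 controls no list kept its call at an estimated correlation. At the preset one, G1/S (0 risen and 7 fallen of 33, adjusted p = 0.000284, and 0.0869), ATF4 targets (4 and 11 of 27, 0.00323, and 0.0783) and NRF2 and metallothionein genes (0 and 6 of 20, 0.00627, and 0.0783) were lower. G2/M (7 and 1 of 30, 0.0206, and 0.0783), heat shock (6 and 0 of 19, 0.0387, and 0.0869) and hypoxia genes (8 and 1 of 35, 0.022, and 0.362) were higher.

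Against cells at 0 h, treated IM-9 cells at 24 h had higher hypoxia genes (22 risen and 0 fallen of 35, median 0.37, adjusted p = 5.66e-17, and 0.00113 with an estimated correlation) and p53 targets (adjusted p = 3.56e-15, and 2.3e-07). Their heat shock (0 risen and 13 fallen of 19, adjusted p = 1.98e-09, and 6.16e-05), G2/M (0 and 15 of 30, 1.95e-07, and 9.09e-05), MYC and ribosome biogenesis (1 and 13 of 27, 3.21e-07, and 9.09e-05) and NRF2 and metallothionein genes (1 and 8 of 20, 0.00662, and 0.0436) were lower, and B cell identity was higher at the preset correlation (0.0164, and 0.0528). Treated U266 cells had higher hypoxia (11 and 0 of 35, 1.57e-08, and 0.0235) and cholesterol biosynthesis genes (4 and 0 of 17, 0.000143, and 0.00259). They also had higher G2/M (0.000262, and 0.00431) and heat shock genes (0.00249, and 0.0197), lists that were higher in the buffer controls as well. Their NRF2 and metallothionein (0.000413, and 0.0159), ATF4 (0.00249, and 0.0573) and G1/S genes (0.0186, and 0.33) were lower. Differences between the lines in these changes were not tested.

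Within all 741 pairs of arrays, the highest share of probes with an identical deposited intensity was 0.223%. Over the called genes of U266 at 1 h, the change correlated across genes with those of the 7 other treatment contrasts between -0.513 (IM-9 at 9 h) and 0.611 (IM-9 at 24 h), genes not being independent replicates. FTL was the brightest probe on 19 of the 20 U266 arrays, so that quantile normalization gave it nearly the same level on each and its U266 values carry no information.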
